A study of Gallus gallus with 12 samples.

How the data were processed

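Breast muscle pieces of 100 mg were kept for RNA, and 100 ng of total RNA per pool was labelled for Affymetrix arrays, per the labels' protocols. The deposited values are one level per transcript cluster and array on a log2 scale, and per the submitters' processing notes GCRMA and Affymetrix Expression Console were used, with no versions or roles given. The base of the logarithm is not stated in the sources used here and was taken as 2 from the values, which run from 0.83 to 14.36, the span of a scanner's range in base 2. GCRMA corrects background by probe sequence and compresses dim signals toward a floor, so differences among dim transcript clusters are imprecise. Array weights, medians and pairwise correlations were checked, and no pair of arrays held the same values.

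Gene names came from the platform annotation: 12300 transcript clusters had 1 symbol, 256 several and 8248 none. Of those with 1 symbol, 11727 were found by gene identifier in RefSeq's gene table for GRCg7b, and 0 symbols changed. Only those with 1 symbol are named. In all, 1644 transcript clusters had exactly the values of another one, 450 of them among those tested, so counts of transcript clusters include some copies.

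Groups came from the labels: 4 arrays each of the normal diet, the restricted diet and the restricted diet plus phytase. Normal replicate 1 has no diet among its listed characteristics, and its group was taken from its title, with the normal diet given in its source name and description. The tests, gene lists, alternatives and the naming rule were fixed before the data were examined. Transcript clusters with a mean at or above the 40th percentile were tested, 12482 in all. A model with 1 mean per diet was fitted to all 12 arrays in limma 3.58.1 (R 4.3.3), with an intensity trend in the prior variance, and Benjamini-Hochberg adjustment was made within each contrast and for an F test over the 3 diets. If no gene passed, the rule named the 24 with the smallest unadjusted p in each contrast, among transcript clusters with 1 symbol and 1 per gene. In the sentences on a list it named members with the smallest p, and W-linked and erythroid markers whatever their p.

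Of 28 gene lists, the 25 with at least 5 tested genes, 1 transcript cluster per gene, were tested with limma's camera at a preset correlation of 0.01, with adjustment over the 25. The lists covered muscle fibres and myogenesis, growth signalling, proteolysis, ribosomes, inositol phosphates, mineral homeostasis, calcium handling, energy metabolism, stress, cell cycle, other cell types of muscle, and sex-linked genes. Camera with an estimated correlation and fry were alternatives. The turning back of diet differences was tested with an exact permutation of array labels.

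The fit was tested on simulated data with 200 changed genes. Simulated data had independent genes, which real arrays do not. The mean number of false calls was 7.1 of 12482 between restricted and normal. The permutation test of turning back gave 2 of 20 simulated data sets without effect an unadjusted p under 0.05, and a median p of 0.599. Alternatives were other filters, normalizations, priors, array weights, a replicate block, an offset of 16, and leaving out each array. A HINTW covariate, leaving out the 4 arrays with HINTW signal, and exact permutation of list scores were added after seeing the data.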

Results

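Expression was measured on Affymetrix arrays in Pectoralis major, the breast muscle, of Ross PM3 chickens at day 36. The birds received a normal diet, a diet restricted in phosphorus and calcium, or the restricted diet supplemented with phytase, an enzyme that releases phosphate from plant phytate. Each of the 12 arrays held a pool of 4 birds, with 4 pools per diet. Values are deposited log2 expression levels of 20804 transcript clusters, of which 12482 were bright enough to be tested. All 3 diet contrasts were examined, to find muscle pathways that the diets may have affected. The number of arrays limits the precision, and the SDs below are spreads between pools, not between birds. The labels do not say how birds were assigned to pools, so the p-values measure the spread between these pools only.

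No transcript cluster differed between diets in limma after Benjamini-Hochberg adjustment at 0.05. The counts of 0 stood beside 662 transcript clusters at an unadjusted p under 0.05 between restricted and normal muscle, 1102 between phytase and restricted muscle, 539 between phytase and normal muscle, and 745 across the 3 diets. Chance alone would give about 624 of the 12482. The genes named below are therefore the 24 with the smallest unadjusted p in each contrast among transcript clusters with 1 symbol, 1 per gene. None of them passed the threshold. Transcript clusters outside this choice can have a smaller p. Between phytase and normal muscle the smallest adjusted p in limma over all clusters was 0.454, in a cluster that was not named. The median standard error of a difference was 0.17 on the log2 scale. In simulated data with the spread of these arrays, the same test recovered 17.8% of genes moved by 0.5, 75.8% of genes moved by 1 and 98.2% of genes moved by 2 between restricted and normal muscle, with 50 genes of each size among 12482. The simulated genes were independent and 200 changed at once, so these shares may not hold for real arrays or for fewer changed genes.

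The restricted diet was compared with the normal diet to describe muscle under low phosphorus and calcium. Globin transcripts stood out: HBA1, the adult alpha globin, was at 6.31 ± 0.25 in normal and 7.79 ± 0.68 in restricted muscle (SD, n = 4), a 2.79-fold difference (limma adjusted p = 0.314, Benjamini-Hochberg). HBAD, the alpha-D globin, was at 7.25 ± 0.19 and 8.92 ± 0.81 (SD, n = 4), a 3.19-fold difference (limma adjusted p = 0.368, Benjamini-Hochberg). All 4 restricted pools lay above all 4 normal pools for both globins, and restricted replicate 3 was the highest. Without that replicate the differences were 1.15 for HBA1 and 1.27 for HBAD on the log2 scale. PLIN1, which coats fat droplets of adipocytes, was higher by 0.75 ± 0.19 (SE) in restricted muscle, with overlapping pools. CTH, which makes cysteine from cystathionine, was lower at -0.56 ± 0.16 (SE). PPID, a cyclophilin, was lower at -0.59 ± 0.15 (SE). COQ6, of coenzyme Q synthesis, was at 3.38 ± 0.21 in normal and 2.63 ± 0.11 in restricted muscle (SD, n = 4), and the restricted level lay under the brightness limit of 2.67 for tested means. With an offset of 16 added before the logarithm, COQ6 differed by -0.25 and CTH by -0.34, and 15 of the 24 genes named in this contrast shrank by over 1.5 times.

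**Figure D1:**
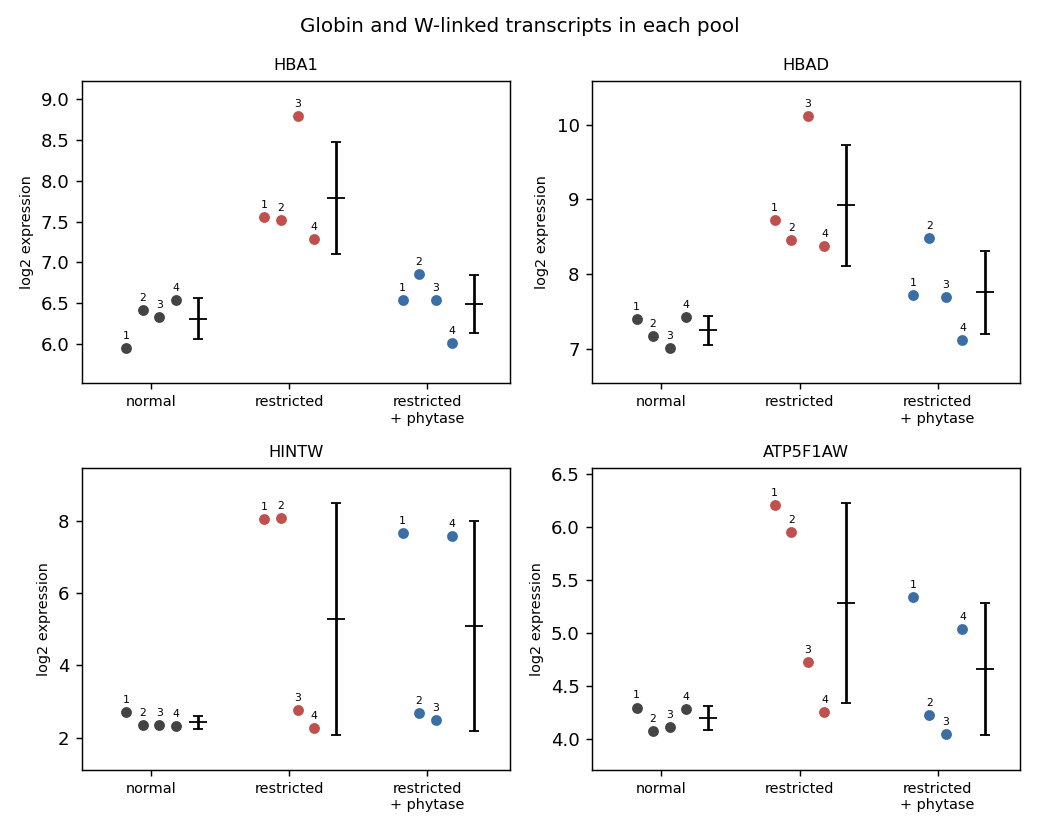
Log2 expression of HBA1, HBAD, HINTW and ATP5F1AW in each of the 4 pools per diet, with points numbered by replicate and bars showing the mean ± SD. Both globins are higher in every restricted pool than in every normal pool, and HINTW is between 7.57 and 8.08 in 4 pools and between 2.27 and 2.76 in the other 8.

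Of the 24 genes, 11 were higher and 13 lower in restricted muscle, with sizes from 0.45 to 1.67 on the log2 scale. The 4 pools of each diet did not overlap for 21 of them, where chance gives 2.86% of genes, but these genes were picked for their small p in the same contrast, so that share is no chance value for them. The higher ones were MRM1, HBA1, HBAD, SH3GL1, PLIN1, ST6GALNAC4, RGS4, FAM78B, PTK2B, EVA1A and CROCC. The lower ones were COQ6, RSBN1, FAM177A1, POP5, PPID, RWDD1, LOC430596, PDZRN3, CTH, STUM, CLIC5, ATP6V0A2 and ZBTB42. HINTW, a W-linked transcript described below, was high in 2 of the 4 restricted and 0 of the 4 normal pools. The count of 662 became 440 without normal replicate 3 and 1073 without restricted replicate 3.

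Among gene lists fixed in advance, 7 of 25 shifted between restricted and normal muscle in camera with a preset correlation of 0.01. Extracellular matrix and fibroblast genes rose, with 28 of 31 higher (adjusted p = 4.2e-05), and this call was lost at an adjusted p = 0.609 with an estimated correlation. In that list TNC, a matrix glycoprotein of remodelling tissue, differed by 1.23 ± 0.56 (SE), FN1, fibronectin, by 0.73 ± 0.34 (SE), TIMP3 by 0.45 ± 0.19 (SE) and COL1A1 by 0.42 ± 0.21 (SE). Erythroid genes rose, with 4 of 5 higher (adjusted p = 0.00422, and adjusted p = 0.495 with an estimated correlation). HBA1 and HBAD were the 2 genes past the threshold when adjusted over the list alone, against 0 over all genes. Adipocyte and lipogenesis genes rose, with 13 of 15 higher (adjusted p = 0.00606, and adjusted p = 0.495 with an estimated correlation). PLIN1 was the 1 adipocyte gene to pass when adjusted over the list alone, against 0 over all genes. The adipocyte call was lost without restricted replicate 4 (adjusted p = 0.113), with a score difference of 0.13 against 0.18. Immediate-early and stress genes rose, with 18 of 23 higher (adjusted p = 0.00711, and adjusted p = 0.609 with an estimated correlation). BTG1 differed by 0.52 ± 0.20 (SE), FKBP5, a glucocorticoid-induced chaperone, by 0.74 ± 0.33 (SE) and JUN by 0.29 ± 0.14 (SE), while ATF3 differed by -0.43 ± 0.25 (SE). Restricted replicate 4 carried much of this, with a list score of 0.37, and without it the score difference went from 0.16 to 0.06 (adjusted p = 0.472 in camera). Genes of macrophages, lymphocytes and antigen presentation rose, with 20 of 25 higher (adjusted p = 0.0180, and adjusted p = 0.668 with an estimated correlation). This list too leaned on restricted replicate 4, with a score of 0.51 against -0.19, 0.08 and -0.04 in the other restricted pools. Without it the score difference went from 0.17 to 0.03 (adjusted p = 0.808 in camera), and the call was also lost without normal replicate 3 (adjusted p = 0.296) or normal replicate 4 (adjusted p = 0.0687), with score differences of 0.08 and 0.16. Heat shock and protein folding genes fell, with 30 of 37 lower (adjusted p = 0.00491, and adjusted p = 0.609 with an estimated correlation). HSPD1, the mitochondrial chaperonin, differed by -0.35 ± 0.15 (SE) and HSPB8 by -0.25 ± 0.11 (SE). Restricted replicate 1 was at a score of -0.35 in this list, and without it the score difference went from -0.14 to -0.05 (adjusted p = 0.288 in camera). Proteasome subunits fell, with 20 of 24 lower (adjusted p = 0.0297, and adjusted p = 0.609 with an estimated correlation), and PSMD12 differed by -0.42 ± 0.18 (SE). The proteasome call was lost without normal replicate 4 (adjusted p = 0.285), restricted replicate 3 (adjusted p = 0.230) or restricted replicate 4 (adjusted p = 0.215). The proteasome score difference was -0.09 with all arrays, and -0.06, -0.08 and -0.08 in these cases. The adjusted p of the other 18 lists ran from 0.101 for slow-fibre genes to 0.987 for MAPK signalling. In the extracellular matrix, immediate-early, macrophage and lymphocyte, heat shock and proteasome lists, 0 genes passed when adjusted over the list alone, and 0 over all genes. The extracellular matrix and erythroid calls were the ones that held whichever single array was left out, although the extracellular matrix score difference went from 0.25 to 0.14 without normal replicate 3. Without the 4 arrays with HINTW signal, left out after seeing the data, the heat shock call was lost and its score difference was -0.01 (adjusted p = 0.764 in camera). With those arrays left out 3 other lists passed: oxidative phosphorylation genes with an adjusted p = 8.7e-05 and ribosomal protein genes with an adjusted p = 0.00598, both lower, and cell cycle genes, higher, with an adjusted p = 0.0424. Their score differences went from -0.06 to -0.15, from -0.02 to -0.08 and from 0.08 to 0.15. Without restricted replicate 4 the count of 7 lists fell to 4.

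Phytase was compared with the restricted diet alone to describe how muscle differed when the enzyme was added to the same restricted diet. HBA1 was lower with phytase, at 6.49 ± 0.35 against 7.79 ± 0.68 (SD, n = 4), a 2.47-fold difference (limma adjusted p = 0.519, Benjamini-Hochberg). Among the genes with higher values with phytase, TTN, the giant spring protein titin, differed by 0.34 ± 0.09 (SE), NRAP, a myofibril assembly protein, by 0.86 ± 0.23 (SE) and IGFN1, a sarcomere-associated protein, by 0.45 ± 0.12 (SE). INPP5K, an inositol polyphosphate 5-phosphatase, differed by 0.60 ± 0.15 (SE) and PPP3CB, a catalytic subunit of calcineurin, by 0.72 ± 0.19 (SE). EGLN3, a prolyl hydroxylase that acts on HIF, differed by 0.55 ± 0.14 (SE).

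Of the 24 genes, 18 were higher and 6 lower with phytase, and the pools of both diets did not overlap for 21. Chance gives 2.86% of genes not picked for their p, so that share is no chance value for these. With an offset of 16, INPP5K differed by 0.25, and 14 of the 24 shrank by over 1.5 times. The higher ones were LOC430596, CCDC53, PTGR2, PTPN21, INPP5K, TTN, IGFN1, MSL3, EGLN3, PPID, MCFD2, RSBN1, PDZRN3, NRAP, SPG20, ZNF830, C2orf49 and PPP3CB. The lower ones were HBA1, ZNF628, NUP43, HSD17B10, CD72 and TANC2. HBA1, PPID, RSBN1, PDZRN3 and LOC430596 were also named between restricted and normal muscle, with the opposite sign. Both contrasts use the same restricted pools, so opposite signs are likely in such genes without any effect. All 24 had an adjusted p of 0.519 in limma with Benjamini-Hochberg adjustment. The count of 1102 became 1727 without restricted replicate 3 and 696 without phytase replicate 2, and it was 587 without the 4 arrays that carried HINTW signal, a comparison chosen after seeing the data.

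In this contrast 4 of 25 lists shifted in camera with the preset correlation. Oxidative phosphorylation genes fell, with 44 of 50 lower (adjusted p = 1.3e-05, and adjusted p = 0.602 with an estimated correlation). UQCRFS1, the Rieske protein of complex III, differed by -0.53 ± 0.17 (SE), UQCR11 by -0.38 ± 0.14 (SE) and ATP5B, of ATP synthase, by -0.36 ± 0.10 (SE). Cytosolic ribosomal protein genes fell, with 39 of 47 lower (adjusted p = 1.0e-04, and adjusted p = 0.602 with an estimated correlation), and RPL38 differed by -0.41 ± 0.15 (SE). Without restricted replicate 2 the ribosomal score difference went from -0.11 to -0.04 (adjusted p = 0.0970 in camera). Cell cycle genes fell, with 17 of 19 lower (adjusted p = 0.00833, and adjusted p = 0.602 with an estimated correlation). E2F1, a transcription factor of S-phase entry, differed by -0.51 ± 0.18 (SE) and TPX2, a spindle protein, by -0.28 ± 0.12 (SE). The cell cycle call was lost without restricted replicate 4, where the score difference went from -0.16 to -0.09 (adjusted p = 0.160). Slow-fibre and fibre-remodelling genes rose, with 13 of 14 higher (adjusted p = 0.00833, and adjusted p = 0.602 with an estimated correlation). CSRP3 differed by 0.85 ± 0.37 (SE), ANKRD1 by 0.64 ± 0.26 (SE) and MB, myoglobin, by 0.49 ± 0.24 (SE). Restricted replicate 1 had a score of -0.78 in this slow-fibre list, far below the other restricted pools. Without it the score difference went from 0.39 to 0.20 (adjusted p = 0.107), and the call was also lost without phytase replicate 4 (adjusted p = 0.142), where the score difference was 0.28. None of these 4 lists had a gene past the threshold when adjusted over the list alone, and 0 passed over all genes. In other lists PPP3CB and CAMK2D of calcium handling, MYLK2 of fast-fibre proteins, and HBA1 and HBAD of the erythroid list passed when adjusted over the list alone, against 0 over all genes. The adjusted p of the other 21 lists ran from 0.0798 for adipocyte genes to 0.987 for proteasome subunits. In the oxidative phosphorylation list restricted replicate 4, at a score of -0.19, was as low as the lowest phytase pool. Without that replicate the score difference was -0.21 against -0.14. The oxidative phosphorylation call was the one that held whichever single array was left out. Without the 4 arrays with HINTW signal it was lost, with a score difference of -0.07 against -0.14 (adjusted p = 0.111), and so was the ribosomal call, with a score difference of 0.01 against -0.11 (adjusted p = 0.971). With those arrays left out 5 other lists passed: erythroid (adjusted p = 0.0146), immediate-early (adjusted p = 0.0146) and macrophage and lymphocyte genes (adjusted p = 0.0453), lower, and myogenic (adjusted p = 0.0421) and calcium handling genes (adjusted p = 0.0421), higher. Their score differences went from -0.38 to -0.57, from -0.11 to -0.20, from -0.09 to -0.17, from 0.13 to 0.17 and from 0.17 to 0.16. The count of 4 lists became 7 without restricted replicate 1, restricted replicate 2 or phytase replicate 2, and 8 without restricted replicate 3.

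**Figure D2:**
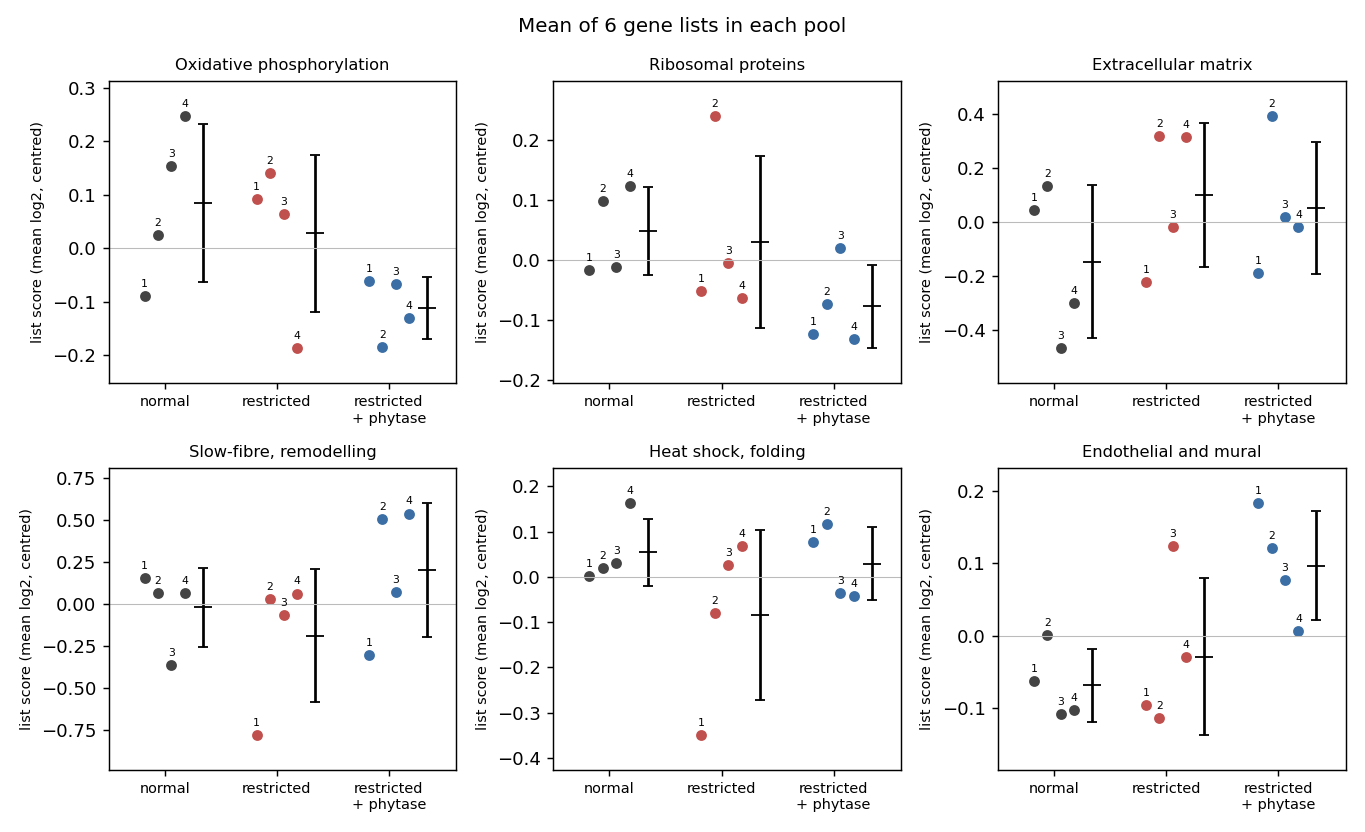
Score of 6 gene lists in each of the 4 pools per diet, as the mean log2 value of the list members after centring each gene on its mean over the 12 arrays, with points numbered by replicate and bars showing the mean ± SD. The oxidative phosphorylation panel shows all 4 phytase pools below 0, together with normal replicate 1 at -0.09 and restricted replicate 4 at -0.19. The slow-fibre panel shows restricted replicate 1 at -0.78.

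Phytase was compared with the normal diet to describe muscle of birds that received the restricted diet and the enzyme together. CD36, a fatty acid transporter, was higher with phytase by 0.72 ± 0.21 (SE), with overlapping pools. ALAD, of heme synthesis, was lower at -0.57 ± 0.15 (SE), and CDC34, a ubiquitin-conjugating enzyme, at -0.51 ± 0.16 (SE). SULF2, which trims heparan sulfate, was higher by 0.56 ± 0.14 (SE) and ROR2, a Wnt receptor kinase, by 0.58 ± 0.16 (SE). With an offset of 16, SULF2 differed by 0.23, ROR2 by 0.23, CD36 by 0.44 and ALAD by -0.35, and 19 of the 24 genes named in this contrast shrank by over 1.5 times. ROR2 was the 1 Z-linked gene to pass when adjusted over the list alone, against 0 over all genes.

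Of the 24 genes, 13 were higher and 11 lower with phytase, and the pools did not overlap for 18. Chance gives 2.86% of genes not picked for their p, so that share is no chance value for these. The higher ones were MRM1, MTF2, SULF2, SH3GL1, VPS50, ROR2, PQLC2, CD36, ZMYND11, FOXN3, PDP2, PRICKLE1 and PRKD1. The lower ones were ALAD, CCDC96, HINT2, GGACT, LRRC20, RASGRF1, LOC693258, TMEM208, KCNC1, CDC34 and DDX49. Their adjusted p in limma with Benjamini-Hochberg adjustment lay between 0.979 and 0.984. HINTW was high in 2 of the 4 phytase and 0 of the 4 normal pools. The count of 539 became 327 without phytase replicate 2, and it was 839 without the 4 arrays with HINTW signal.

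In this contrast 7 of 25 lists shifted in camera with the preset correlation. Oxidative phosphorylation genes fell, with 48 of 50 lower and a median difference of -0.20 (adjusted p = 6.3e-14, and adjusted p = 0.495 with an estimated correlation). NDUFB2, of complex I, differed by -0.37 ± 0.13 (SE), UQCRFS1 by -0.41 ± 0.17 (SE) and ATP5I by -0.30 ± 0.12 (SE). Ribosomal protein genes fell, with 44 of 47 lower and a median difference of -0.12 (adjusted p = 3.7e-08, and adjusted p = 0.601 with an estimated correlation). RPL13 differed by -0.29 ± 0.12 (SE) and RPS2 by -0.20 ± 0.08 (SE). Proteasome subunits fell, with 18 of 24 lower (adjusted p = 0.0199, and adjusted p = 0.636 with an estimated correlation). That call was lost without normal replicate 4 (adjusted p = 0.245), phytase replicate 2 (adjusted p = 0.0543) or phytase replicate 4 (adjusted p = 0.158). The score difference was -0.08 with all arrays, and -0.04, -0.07 and -0.05 in these cases. Without the 4 arrays with HINTW signal it was -0.07 and the call was lost (adjusted p = 0.0824). Extracellular matrix genes rose, with 29 of 31 higher (adjusted p = 0.00306, and adjusted p = 0.636 with an estimated correlation), and TIMP3 differed by 0.51 ± 0.19 (SE). The extracellular matrix score difference went from 0.20 to 0.09 without normal replicate 3 (adjusted p = 0.270), to 0.15 without normal replicate 4 (adjusted p = 0.126) and to 0.08 without phytase replicate 2 (adjusted p = 0.266). Satellite cell and myogenic regulator genes rose, with 13 of 16 higher (adjusted p = 0.00306, and adjusted p = 0.601 with an estimated correlation), among them MEF2A at 0.34 ± 0.18 (SE). The myogenic score difference went from 0.22 to 0.15 without normal replicate 3 (adjusted p = 0.0550) or phytase replicate 2 (adjusted p = 0.0543). Calcium handling and calcineurin genes rose, with 20 of 24 higher (adjusted p = 0.0122, and adjusted p = 0.601 with an estimated correlation), among them PPP3CB at 0.52 ± 0.19 (SE) and NFATC1 at 0.33 ± 0.15 (SE). Phytase replicate 4 stood apart in the calcium list, with a score of -0.11, below all 4 normal pools, against 0.15 to 0.19 in the other phytase pools. The calcium call was lost without normal replicate 2 (adjusted p = 0.0731) or phytase replicate 1 (adjusted p = 0.0717), with score differences of 0.13 and 0.12 against 0.15. Endothelial and mural genes rose, with 14 of 18 higher (adjusted p = 0.0107, and adjusted p = 0.223 with an estimated correlation). PECAM1, an endothelial adhesion molecule, differed by 0.50 ± 0.21 (SE) and MYH11, smooth muscle myosin, by 0.70 ± 0.29 (SE). The endothelial call was lost without normal replicate 4 (adjusted p = 0.0536), with a score difference of 0.15 against 0.17. It was also lost without the 4 arrays with HINTW signal (adjusted p = 0.0824), where the score difference was 0.17. Slow-fibre genes passed with those arrays left out (adjusted p = 0.0317), with a score difference of 0.31 against 0.22. No gene of these 7 lists passed when adjusted over the list alone, and 0 passed over all genes. The adjusted p of the other 18 lists ran from 0.107 for glycolysis to 0.901 for phosphate and vitamin D genes. The oxidative phosphorylation and ribosomal calls were the ones that held whichever single array was left out, and the count of 7 fell to 4 without normal replicate 4 or phytase replicate 2. In the oxidative phosphorylation list normal replicate 1, at a score of -0.09, lay below phytase replicates 1 and 3, at -0.06 and -0.07.

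The lists closest to the diets themselves did not shift in any contrast in camera after adjustment. The 50 tested genes of inositol and inositol phosphate metabolism had median differences of -0.01 between restricted and normal muscle, 0.04 between phytase and restricted muscle and 0.04 between phytase and normal muscle. In an exact permutation of list scores, added after results were seen, the last contrast had an unadjusted p = 0.0286 and an adjusted p = 0.238. IMPA1, inositol monophosphatase, differed by -0.66 ± 0.21 (SE) between restricted and normal muscle, and PPIP5K1, an inositol pyrophosphate kinase, by 0.47 ± 0.17 (SE). The 22 tested genes of phosphate, vitamin D and calcium homeostasis had median differences of 0.04, -0.07 and 0.02 in the same order. In that list ATP2B1, a plasma membrane calcium pump, differed by 0.52 ± 0.17 (SE) between phytase and restricted muscle and FGFR4 by -0.34 ± 0.13 (SE). No gene of either list passed when adjusted over the list alone, and 0 passed over all genes.

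Whether phytase turned back the differences seen with the restricted diet was tested over all 12482 transcript clusters, with the restricted pools split so that no pool entered both contrasts. The mean correlation across genes was -0.02 over 6 splits, from -0.13 to 0.08, and genes are not independent replicates. An exact one-sided permutation test over 34650 relabelings gave p = 0.432, so no turning back was detected. With the shared restricted pools left unsplit, r was -0.58 against -0.50 simulated with no effect, and the covariance was -0.035 against -0.021 simulated. That simulation drew independent genes with the same spread in every array. In the real data restricted replicates 1 and 3 had the lowest array weights, 0.49 and 0.56. The gap between real and simulated values is therefore no evidence of turning back.

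W-linked transcripts, which only hens carry, separated pools within diets. HINTW was at 8.06, 8.08, 2.76 and 2.27 in restricted replicates 1 to 4, and at 7.66, 2.69, 2.48 and 7.57 in phytase replicates 1 to 4. It was at 2.43 ± 0.18 in normal muscle (SD, n = 4). ATP5F1AW was at 6.21 and 5.96 in restricted replicates 1 and 2 and at 5.34 and 5.04 in phytase replicates 1 and 4, and between 4.05 and 4.73 in the other 8 arrays. It was the 1 of 2 tested W-linked genes to pass between restricted and normal muscle when adjusted over the list alone, against 0 over all genes. The signal was thus present in 0 of 4 normal, 2 of 4 restricted and 2 of 4 phytase pools. Lists with fewer than 5 tested genes were not put to the list test: W-linked genes with 2, mitochondrially encoded transcripts with 3, and nerve and Schwann cell genes with 2.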

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

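The tests of hens and of a single array as sources of the globin difference, and both tests on oxidative phosphorylation, were chosen only after the result was seen. The test of hens on oxidative phosphorylation replaced a first comparison that decided nothing, in which the higher phytase array without HINTW signal lay 0.0218 above the lowest normal array. The count of transcript clusters that share the HINTW pattern was also made stricter after a first count, from 27 to 12, by counting copies once and leaving out those annotated to HINTW.

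HINTW signal was present in 4 of the 12 arrays and in none of the normal arrays. A single cross-hybridising probe set is argued against, because 12 other distinct transcript clusters separated the same 4 arrays from the other 8 by over 1 on the log2 scale, while the highest count among 494 other choices of 4 arrays was 1. Hens in these pools may be the source. The 15 tested Z-linked genes, of which hens carry a single copy, had a median difference of -0.225 between arrays with and without the signal within diets, but an exact one-sided permutation over 36 relabelings gave p = 0.0833, and the difference was -0.47 in restricted and -0.01 in phytase arrays. The labels do not give the sex of the birds. Arrays without the signal exist in every diet, but no normal array has it. The source of the signal is therefore partly confounded with diet in both contrasts against normal muscle.

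Globin transcripts were higher in the restricted arrays, with a mean of 8.36 ± 0.75 against 6.78 ± 0.15 in normal arrays (SD, n = 4), and since HBA1 and HBAD were also among the genes with the smallest p in this contrast, no p is given for their mean. A single array is argued against, since the lowest restricted array lay 0.855 above the highest normal one. Hens are argued against, since the restricted arrays without HINTW signal also lay at least 0.855 above. A choice of genes for their small p favours such gaps, so they describe these arrays and say nothing of chance. More blood left in the pieces could account for it and stays open: the 3 other tested erythroid genes had a median difference of 0.198 against a limit of 0.2 set beforehand, but CA2 at -0.39, AQP1 at 0.40 and TFRC at 0.20 spread by 0.41 (SD), which leaves it undecided. AQP1 was at 4.65 in normal, 5.04 in restricted and 5.55 in phytase arrays, and CA2 at 8.05, 7.66 and 8.14. Neither followed the globins across the diets, so these 3 genes may not report blood content and their median cannot decide the question. SLC4A1, the red cell anion exchanger, was too dim to be tested and was at 2.15 ± 0.21 in normal, 2.81 ± 0.25 in restricted and 2.19 ± 0.26 in phytase arrays (SD, n = 4), a gene singled out after its values were seen. EPB42, also too dim to be tested, differed by 0.25 between restricted and normal arrays. The remaining untested erythroid transcripts outside the globins differed little or went the other way: RHCE by -0.19 and -0.30, HEMGN by -0.02 and RHAG by 0.01. The median over all 10 listed transcript clusters outside the globins was 0.05.

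Oxidative phosphorylation genes were lower in the phytase than in the normal arrays. A smaller share of muscle fibre would lower the glycolysis list as much. In these pools its median difference was -0.0525, smaller than the median of -0.20 for oxidative phosphorylation. The 95% bootstrap interval of the glycolysis median, from -0.0963 to -0.0238, lay above -0.20. That bootstrap drew genes and not pools, so it leaves out the spread between pools and does not decide the question. Hens as the whole source are argued against, since within diets the list mean was 0.1037 higher in arrays with HINTW signal (95% interval from -0.08 to 0.29), where -0.39 would be needed. Without the 4 arrays with the signal the difference was -0.21 against -0.20, and the list still passed in camera with the preset correlation (adjusted p = 1.17e-09). With all arrays this call was lost in camera with an estimated correlation (adjusted p = 0.495). An effect of the diet stays open as a hypothesis, and an exact permutation test of the list score gave p = 0.0857.

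Other splits of the arrays gave as many transcript clusters at an unadjusted p under 0.05 too often to exclude chance. For restricted against normal, 12 of 35 splits gave at least the real 662, and the highest other gave 1504. For phytase against restricted, 4 of 35 splits reached 1102, with 2325 the highest other. That highest split set restricted replicates 1, 2 and 4 with phytase replicate 4 against the rest. Among all the other splits the highest count at an adjusted p under 0.05 in limma was 348, which points to a structure among the arrays that the diets do not describe. The split of these arrays by HINTW signal gave 945 at an unadjusted p under 0.05. For phytase against normal, 10 of 35 splits reached 539, with 1150 the highest other, and over the 3 diets 27 of 100 drawn splits reached 745, with 1715 the highest other.

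In 15 of 279 groups of 4 pools, 1 pool stood far from the other 3, where chance gives about 14. The gap to the nearest pool as a share of the range was 0.909 for CTH in phytase replicate 3, 0.846 for CCDC53 in normal replicate 2 and 0.968 for CCDC53 in restricted replicate 1. It was 1 for INPP5K in phytase replicate 1, whose value of 3.84 lay below 3.88 in each of the other pools. It was 0.864 for TTN in normal replicate 2, 0.837 for ROR2 in normal replicate 3, 0.875 for ZMYND11 in normal replicate 1 and 0.891 for CDC34 in restricted replicate 1. Among lists it was 0.848 for slow-fibre genes and 0.845 for calcium handling genes, both low in restricted replicate 1, and 0.861 for calcium handling genes in phytase replicate 4. It was 0.915 for proteasome subunits in normal replicate 4, 0.873 for proteasome subunits in restricted replicate 2, 0.835 for erythroid genes in normal replicate 4 and 0.921 for HINTW in normal replicate 1.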

How the results depend on the processing

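The HINTW covariate, the arrays left out for HINTW signal, the permutation of list scores and the alternatives to the counts at an unadjusted p were chosen only after results were seen. The count of 0 transcript clusters in limma held in each contrast under every other filter, normalization, prior and left-out array that was run. An unadjusted threshold gave 662 (restricted against normal), 1102 (phytase against restricted), 539 (phytase against normal) and 745 (any diet). Without a filter, which tests more transcript clusters, 662 became 1040 and 539 became 882, and with a filter at the 60th percentile 539 became 341. For phytase against normal, array weights gave 895, the HINTW covariate 1029 and leaving out the 4 arrays with HINTW signal 839, and leaving them out gave 587 for phytase against restricted; the cause was not tested. Leaving out single arrays gave 440 to 1073, 696 to 1727, 327 to 687 and 495 to 1233 in the order above, the last from 745. The lows came without normal replicate 3 for the first and phytase replicate 2 for the others, and the highs without restricted replicate 3, or phytase replicate 4 for phytase against normal.

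The calls of 7, 4 and 7 lists depended on the preset correlation. An estimated correlation gave 0, 0 and 0 lists, fry gave 0, 0 and 0, and exact permutation of list scores gave 1, 0 and 3 at an unadjusted p under 0.05, where 0.0286 is the smallest p that 4 against 4 can give. Single arrays left out gave 4 to 10, 3 to 8 and 4 to 9 lists, and 9, 7 and 6 lists passed without the 4 arrays with HINTW signal, with 5 calls lost and 9 gained over the 3 contrasts; the cause was not tested. The turning back of diet differences changed sign to 0.14 without those 4 arrays and ran from -0.15 to 0.12 with single arrays left out; the cause was not tested. Over transcript clusters with an F test p under 0.05 it was -0.46, and p was 0.436 over 100 drawn relabelings that each chose their own clusters, beside 0.432 over all clusters. None of 1440 recomputed values of named genes changed sign, which says nothing of stability, since the genes were picked for a small p and several settings cannot move a difference of means. Of the gene list values 1517 stayed called or stayed uncalled, 85 lost the call and 48 gained it. Most of the 1517 were uncalled in both settings, so that number says little of stability. The exact permutation gave 16 of the losses and 2 of the gains, and was counted at an unadjusted p, unlike the other settings. Direction was not compared where a list was uncalled in both settings. The replicate block gave 0 adjusted calls and 623, 1072, 518 and 722 at an unadjusted p; the same numbers do not pair the arrays, since correlations of the 12 same-numbered pairs ran from -0.16 to 0.18 and 2 arrays correlated best with their own number. An offset of 16 before the logarithm shrank the differences of dim genes, such as MRM1 from 0.66 to 0.23 between restricted and normal, so signal near the background limits these genes.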

Other observations

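The test named here was added only after list results were seen. Taking each list as 1 score per array, an exact permutation test put 3 lists at p = 0.0286 between phytase and normal arrays, the smallest p that 4 against 4 can give. They were endothelial and mural genes with a score difference of 0.17, myostatin, TGF-beta and BMP signalling genes with 0.10, and inositol phosphate genes with 0.05. Over the 25 lists their adjusted p was 0.238 in the exact permutation test, so none passed. Erythroid genes, with a score difference of 0.67, reached p = 0.0286 in the same exact test between restricted and normal arrays, with an adjusted p of 0.714.

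BMP4, a bone morphogenetic protein, differed by 0.41 ± 0.14 (SE) between restricted and normal arrays and by -0.43 ± 0.14 (SE) between phytase and restricted arrays, the smallest unadjusted p of its list in both. MSTN, the muscle growth inhibitor myostatin, went the other way and differed by -0.45 ± 0.30 (SE) between restricted and normal arrays and by 0.58 ± 0.30 (SE) between phytase and restricted arrays. The same restricted pools enter both contrasts, so opposite signs are likely without any effect. No gene of that list passed in limma when adjusted over the list alone, with a smallest adjusted p of 0.286 and 0.195 in these contrasts. The 16 tested satellite cell genes and the 31 tested genes of insulin and mTOR signalling had median differences of 0.06 and -0.04 between restricted and normal arrays.

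The first principal component held 22.3% of the variance and set restricted replicate 1 at 39.77, with restricted replicate 2 at 18.62 and phytase replicate 4 at 15.53. The same array had the lowest array weight, 0.49, followed by restricted replicate 3 at 0.56.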
